A study of Mus musculus with 14 samples.

How the data were processed

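Nuclei were isolated from punches of prefrontal cortex and libraries were made with the 10x Genomics 3' kit v3.1 for a target of 10000 nuclei per animal, per the labels' protocols. Reads were processed with Cell Ranger 6.1.2 and Seurat 4.3.0 against mm10, per the submitters' processing notes. The values used here are the deposited counts, whole numbers of UMIs per gene and nucleus, with a deposited table that gives each nucleus its animal, group, cell type name and cluster. The filters that the authors applied to nuclei, any treatment of doublets or free RNA, and whether reads were subsampled between libraries are not given in the sources used here. All 157620 nuclei were kept, with no further filter and no doublet caller. They had from 233 to 261563 UMIs each and up to 29.3% mitochondrial UMIs. The group named in the table and the barcode suffix matched for all 157620 nuclei. Each group was taken from the labels' titles, which give an animal number that no animal of the other group shares, so animals were not paired. Each animal was 1 replicate, and pairwise correlations of log2 CPM over all nuclei, across genes, lay between 0.984 and 0.998, so no library was a copy of another.

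The authors' 19 type names were used as given and combined into 7 broad classes. Excitatory neurons and inhibitory neurons held 6 types each, and astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia and vascular cells (the mural type) 1 each. Nuclei named macrophages or T cells were compared only at the level of types. Clusters of the authors were given a class by hand after their values were seen, where markers of that class, fixed before the data were examined, stood among their 10 leading genes. Cluster 8, with no marker among its leading genes, was classed with inhibitory neurons by its Gad1 (708 CPM), a choice made after its values were seen. Leading genes had at least 20 CPM and were ordered by fold over all other nuclei, with 5 CPM added to both levels. Clusters 12, 17, 19, 20, 26, 28, 29, 30 and 31, called mixed here, were left without a class by judgement, although in each but cluster 30 the fixed markers among the 10 leading genes were of 1 cell type. Median UMI counts in clusters 12, 17, 19, 26, 28 and 29 lay between 6138 and 14070, above those of the clusters classed by the same markers, and Aqp4 stood at 69.0, 151 and 114 CPM in clusters 20, 30 and 31. CPM stands for a gene's counts as a share of the summed counts of an animal and class, on the usual CPM scale.

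Counts were summed per animal and class, for animals with at least 20 nuclei. Genes were kept by filterByExpr with a minimum count of 10 and the groups were compared with edgeR 4.0.16 in R 4.3.3, with TMM normalization and the robust quasi-likelihood F test, which is two-sided. P-values were adjusted by Benjamini-Hochberg within each class, with a threshold of 0.05. Standard errors of log2 fold changes were the fold change divided by the square root of F. Every adjusted p of a gene came from edgeR unless DESeq2 or limma is named. Shares of nuclei, depths and totals were compared by exact two-sided permutation tests over all 3003 splits of the 14 animals, adjusted over the types of 1 level. The difference of the vapor effect between neuron classes was an interaction term with the animal as a block.

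Of 34 gene lists fixed before the data were examined, 2 had fewer than 5 measured members in every class. The others were tested by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over all 221 pairs of list and class, with an estimated correlation and with fry beside it. A gene was named if it was among the 8 higher or 8 lower called genes of a class with the smallest p (3 and 3 for all nuclei and for each type), or a called member of a fixed list. Predicted gene models were counted and not named. In a class with no call the 3 genes with the smallest p were given as values. Cpa6 and Gpc5 were given in every class, and of a list that did not change the 2 most abundant members, some of which are not reported here. Genes named outside this rule are marked as chosen after their values were seen, and so were the values of Phyhd1, Zfhx3 and Ppfibp1 in clusters and the members named as examples of a list. Coordinates were taken from GENCODE vM21 on GRCm38, in which 32158 of the 32285 gene identifiers were found, and 38 symbols stood for more than 1 identifier.

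Alternatives set before the data were examined were DESeq2 1.42.0, RLE normalization, no expression filter, at least 50 nuclei per animal, each animal left out in turn, adjustment over all classes together, a threshold of 0.1, the median UMIs per nucleus as a covariate, shares on a log2 scale or from nuclei with at least 1000 UMIs, and limma-voom for the interaction. Chosen after seeing the data were classes rebuilt from clusters, only nuclei whose name and cluster gave 1 class, leaving out clusters 8, 11, 22 and 24, cluster 0 or the mixed clusters, leaving out the 5 animals with over 10% of nuclei in clusters 8, 11, 22 and 24, and the log2 of that share as a covariate. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 made the sums and tables.

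The tests were checked on counts simulated from the real means and library sizes with 200 changed genes. Each gene was drawn independently around a common mean profile, so differences between animals shared by many genes were not simulated. For astrocytes, with 14134 genes run, 48.5% of genes changed by 1.5-fold, 84.6% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 7 false calls. For oligodendrocytes, with 12407 genes run, these were 24.2%, 69.8% and 100%, with 5 false calls. For excitatory neurons, with 19230 genes run, they were 52.2%, 77.6% and 100%, with 9 false calls. For the interaction, 200 genes were changed 4-fold in excitatory neurons alone, and 188 of them were recovered among 17726, with 17 false calls. Smaller changes were not simulated for the interaction.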

Results

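Single nuclei from the prefrontal cortex of 14 male C57BL/6J mice, an inbred laboratory strain, were profiled by droplet sequencing of the 3' ends of RNA. Of the 14 mice, 6 had been exposed to intermittent ethanol vapor, a model of alcohol dependence, and 8 had been kept in chambers with air. Each of the 5 cycles had 4 days of vapor, with 16 h on and 8 h off, then 4 days with 2 h sessions in which both groups could drink 15% ethanol or water, then 72 h of abstinence. Tissue was taken 3 to 5 h after the last vapor. The files held 157620 nuclei and 32285 genes, from 5000 nuclei in air animal 19 to 14968 in air animal 29. Summed UMIs (unique transcript molecules) ranged from 34834511 to 105689625 per animal. No difference was detected between the 6 vapor and 8 air animals (two-sided exact permutation test, p = 0.628). Over all nuclei the median was 4171 UMIs, 2177 genes and 0.279% mitochondrial UMIs. The median mitochondrial percent per animal averaged 0.238 ± 0.123 (SD, n = 6) in vapor and 0.331 ± 0.185 (SD, n = 8) in air animals (exact p = 0.312).

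The study asks how alcohol dependence changes gene expression in each cell type of the prefrontal cortex, so the authors' cell type names were taken first. Mbp, the myelin basic protein, stood at 1802 CPM (counts scaled to a common total) in nuclei named oligodendrocytes and at 166 CPM in those named astrocytes, and Aqp4, the astrocytic water channel, at 145 CPM in astrocytes and 15.7 CPM in oligodendrocytes. Gad2, an enzyme of GABA synthesis, ranged from 72.7 to 228 CPM over the 6 inhibitory types and from 16.4 to 32.8 CPM over the 6 excitatory types. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, separated the types little, with 205 CPM in the type Excit_E and 185 CPM in astrocytes. A UMI of Slc17a7 was found in 86.6% of Excit_E nuclei (median 11335 UMIs) and in 40.4% of astrocytes (median 2698 UMIs). Since its CPM lay between 139 and 270 in all 19 types, its UMIs were not read as expression in glia, and whether they came from free RNA or from misnamed or mixed nuclei was not tested. Of the nuclei in clusters that were given a class, the authors' name and cluster gave the same class for 94.7% of excitatory neurons, 89.4% of oligodendrocytes, 88.0% of vascular cells and 87.4% of astrocytes. It did so for 69.6% of microglia, 61.0% of inhibitory neurons and 51.5% of oligodendrocyte precursors. These percentages leave out the nuclei in clusters without a class. Such nuclei were 42.19% of microglia, 38.82% of inhibitory neurons, 37.19% of vascular cells and 30.77% of astrocytes. They were 30.13% of oligodendrocyte precursors, 18.81% of excitatory neurons and 16.35% of oligodendrocytes. Cluster 0 held 30257 nuclei with a median of 1118 UMIs and was led by mitochondrial genes such as mt-Atp6 and mt-Co2. Of the 8174 nuclei named T cells, 29 (0.355%, median 2748 UMIs) had a UMI of Cd3e, a T cell receptor component, beside 0.132% of nuclei named mural cells (median 2263 UMIs), which should lack it.

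A group of 4 clusters differed widely in size between animals. Cluster 8 was led by Adamts19, Dnah11 and Cpa6, cluster 11 by Pde1c, Stac and Lgr5, with Calb2 and Th, cluster 22 by the olfactory receptor genes Olfr111 and Olfr115 and by Cdhr1, and cluster 24 by Sntb1, Mybpc1 and Col11a1. Together clusters 8, 11, 22 and 24 held 0.253% of the nuclei of vapor animal 26 and 32.3% of those of air animal 19. The mean share was 3.63 ± 4.58% (SD, n = 6) in vapor and 12.4 ± 11.3% (SD, n = 8) in air animals. The vapor mean was 8.80 points lower, and the exact test did not detect a difference (p = 0.101), which does not show that the groups were balanced. Among vapor animals the share was 0.428% in animal 2, 0.655% in animal 9, 4.33% in animal 16, 3.92% in animal 33 and 12.2% in animal 34. Among air animals it was 19.5% in animal 5, 4.47% in animal 17, 0.705% in animal 20 and 10.9% in animal 21. It was 22.2% in animal 22, 0.474% in animal 24 and 8.94% in animal 29.

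**Figure D1:**
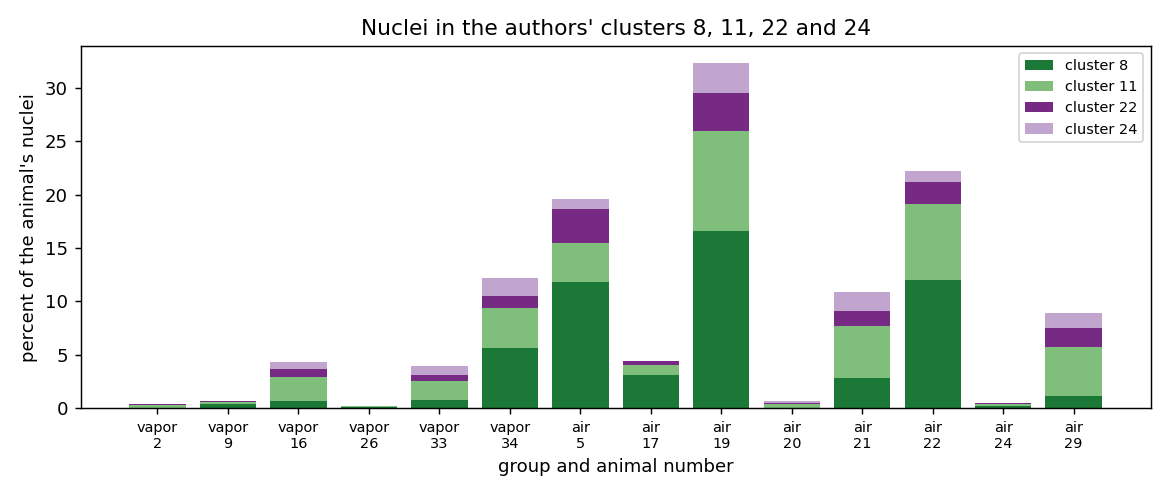
Percent of each animal's nuclei (y axis) in the authors' clusters 8, 11, 22 and 24 (stacked colours) for the 6 vapor and 8 air animals (x axis, by animal number). The stacks range from 0.253% in vapor animal 26 to 32.3% in air animal 19.

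Whether vapor exposure altered the make-up of the tissue was addressed with the share of each animal's nuclei per class. Oligodendrocyte precursors made up 4.01 ± 0.248% (SD, n = 6) of nuclei in vapor and 4.76 ± 0.713% (SD, n = 8) in air animals (exact p = 0.0230), which did not pass adjustment over the 7 classes (adjusted p = 0.161). Cluster 15, led by the precursor markers Pdgfra and Vcan, went the other way. It held 2.16 ± 0.452% of nuclei in vapor and 1.88 ± 0.453% in air animals (exact p = 0.275, adjusted p = 0.444 over the clusters). The lower share of named precursors was thus not seen in the precursor cluster. Oligodendrocytes stood at 8.04 ± 1.58% and 6.56 ± 1.31% (exact p = 0.0759, adjusted p = 0.246). Excitatory neurons made up 35.3 ± 5.17% in vapor and 30.4 ± 5.26% in air animals (exact p = 0.108, adjusted p = 0.246), and inhibitory neurons 26.4 ± 3.29% and 30.6 ± 5.65% (exact p = 0.141, adjusted p = 0.246). No difference was detected in astrocytes (8.36 ± 0.763% and 8.33 ± 0.900%, exact p = 0.941), microglia (4.08 ± 0.439% and 4.01 ± 0.913%, exact p = 0.868) or vascular cells (5.51 ± 1.01% and 6.62 ± 1.74%, exact p = 0.186). Among the authors' 19 types, Excit_F had the smallest p, with 8.55 ± 1.47% in vapor and 6.51 ± 1.19% in air animals (exact p = 0.00932, adjusted p = 0.177), and none passed adjustment. Leaving out 1 animal carried 2 shares past adjustment. One was that of oligodendrocyte precursors without air animal 17 (exact test, adjusted p = 0.0449). The other was that of Excit_F without vapor animal 34 (exact test, adjusted p = 0.0443).

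**Figure D2:**
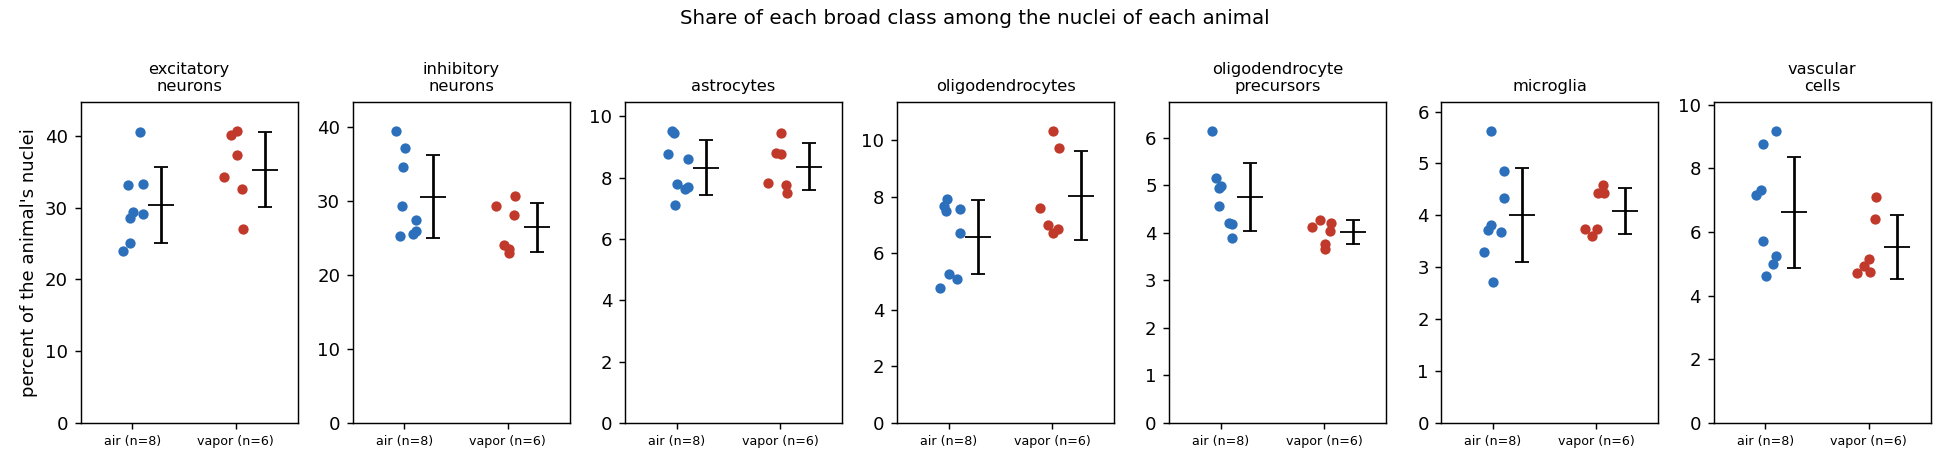
Percent of each animal's nuclei (y axis, from 0) in each of 7 broad classes, with 1 dot per animal (air n = 8, vapor n = 6) and the mean ± SD beside the dots. Oligodendrocyte precursors averaged 4.01% in vapor and 4.76% in air animals, and the dots of the groups overlap in every class.

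In astrocytes, edgeR called 2 genes lower in vapor animals and none higher. Phyhd1, which encodes an iron-dependent dioxygenase, stood at 36.0 ± 6.83 CPM (SD, n = 6) in vapor and 79.0 ± 15.8 CPM (SD, n = 8) in air animals, a log2 fold change of -1.12 ± 0.14 (SE; edgeR adjusted p = 0.00297). Zfhx3, a homeodomain transcription factor, stood at 56.0 ± 8.48 and 132 ± 33.1 CPM, a log2 fold change of -1.21 ± 0.16 (SE; edgeR adjusted p = 0.00399). For both genes, all 6 vapor animals lay below every air animal. Phyhd1 (ENSMUSG00000079484) lies on chromosome 2 from 30266203 to 30282149 on the plus strand of GRCm38, and Zfhx3 (ENSMUSG00000038872) on chromosome 8 from 107942644 to 108961630 on the plus strand. Over the authors' cluster 5, led by astrocyte genes, Phyhd1 stood at 39.6 ± 10.1 and 104 ± 23.4 CPM (log2 fold change -1.41 ± 0.16, edgeR adjusted p = 0.000379) and Zfhx3 fell too, with -1.17 ± 0.17 (adjusted p = 0.00562). In that cluster Mfsd2a, a transporter of lysophospholipids, was also called, at 17.95 ± 4.73 and 34.74 ± 5.045 CPM (log2 fold change -0.94 ± 0.16, adjusted p = 0.0486). It was chosen after its values were seen. The heparan sulfate proteoglycan Gpc5, chosen before the data were examined, stood at 4878 ± 1279 and 4210 ± 789 CPM (log2 fold change 0.25 ± 0.17, adjusted p = 0.871). Cpa6, a carboxypeptidase chosen likewise, stood at 29.5 ± 21.1 and 64.1 ± 48.2 CPM (log2 fold change -1.06 ± 0.53, adjusted p = 0.744). The astrocyte sums held 1680919 to 5928792 UMIs per animal, and of 14252 genes tested 1012 had an unadjusted p under 0.05. DESeq2 called 40 genes, both of these among them and 6 of the 40 higher in vapor animals. One of the 6 was Tnfaip8 (log2 fold change 0.63, DESeq2 adjusted p = 0.000305), chosen after its values were seen, which edgeR called higher with no expression filter, with the median UMIs as a covariate, without cluster 0 and without air animal 17 or vapor animal 34 (edgeR adjusted p from 0.0185 to 0.0398). The other 34 were lower, and Bnc2 (-2.08), Eya2 (-1.79) and Ptgds (-1.10) among them (DESeq2 adjusted p = 0.0260, 0.0496 and 0.0490) also stand among the 10 leading genes of cluster 20. Aldh1a2 (-1.79) and Slc22a8 (-1.39), known from the meninges, were lower too (DESeq2 adjusted p = 0.00364 and 0.00448), and these 5 were chosen after their values were seen. Cluster 20 held 0.865 ± 0.244% of nuclei in vapor (n = 6) and 1.96 ± 1.16% in air animals (n = 8; exact p = 0.0476, adjusted p = 0.265). The edgeR count was 7 without air animal 17 and 2 or 3 without any other animal. It was 1 without the 5 animals with over 10% of nuclei in clusters 8, 11, 22 and 24, where Zfhx3 had a log2 fold change of -0.99 (adjusted p = 0.172).

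In oligodendrocytes, edgeR called 2 genes lower in vapor animals and none higher. Ppfibp1, which encodes a liprin scaffold protein, stood at 15.0 ± 2.49 CPM (SD, n = 6) in vapor and 36.7 ± 8.71 CPM (SD, n = 8) in air animals (log2 fold change -1.28 ± 0.18, edgeR adjusted p = 0.0105). All 6 vapor animals lay below every air animal. Phyhd1 stood at 15.5 ± 3.67 and 34.7 ± 9.88 CPM (log2 fold change -1.23 ± 0.20, edgeR adjusted p = 0.0337), with 5 of the 6 vapor animals below every air animal. These rest on 18 to 99 counts per animal for Ppfibp1 (ENSMUSG00000016487, chromosome 6, 146888487 to 147032025, plus strand of GRCm38) and on 20 to 131 for Phyhd1. Over the authors' cluster 4, led by oligodendrocyte genes, Phyhd1 stood at 9.35 ± 3.45 and 35.3 ± 13.1 CPM (log2 fold change -1.99 ± 0.26, adjusted p = 0.00154). Ppfibp1 stood at 13.1 ± 4.48 and 20.2 ± 9.66 CPM there and was not called (-0.54 ± 0.25, adjusted p = 0.999). Ptgds, the prostaglandin D synthase, was called in cluster 4 at 706 ± 224 and 1757 ± 504 CPM (-1.31 ± 0.21, adjusted p = 0.0132). It too was chosen after its values were seen, and it is also a leading gene of cluster 20, at 11595 CPM against 269 CPM in other nuclei. In nuclei named astrocytes Ppfibp1 had a log2 fold change of -0.33 ± 0.16 (adjusted p = 0.706), and in those named oligodendrocytes Zfhx3 had a log2 fold change of -0.17 ± 0.21 (adjusted p = 0.950). Whether either value differed between the classes was not tested. Gpc5 stood at 166 ± 50.6 and 158 ± 37.7 CPM (0.06 ± 0.19, adjusted p = 0.989) and Cpa6 at 57.6 ± 59.6 and 244 ± 270 CPM (-2.12 ± 0.93, adjusted p = 0.543). The oligodendrocyte sums held 835489 to 3255244 UMIs, and of 12572 genes tested 1095 had an unadjusted p under 0.05. DESeq2 called 46 genes, 27 of them higher in vapor animals, with no adjusted p for these 2. Among the 27 was the transcription factor Npas3 (log2 fold change 0.95, DESeq2 adjusted p = 0.000214), chosen after its values were seen. With no expression filter edgeR called 13 genes, 9 of them higher. The edgeR count was 0 without vapor animal 2, 33 or 34, and 1 without vapor animal 9 or 16 or air animal 17, 19, 20, 21 or 22. It was 4 (1 higher) without air animal 5, 6 (4 higher) without air animal 24, 8 (4 higher) without the mixed clusters, and 0 with the share of clusters 8, 11, 22 and 24 as a covariate.

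**Figure D3:**
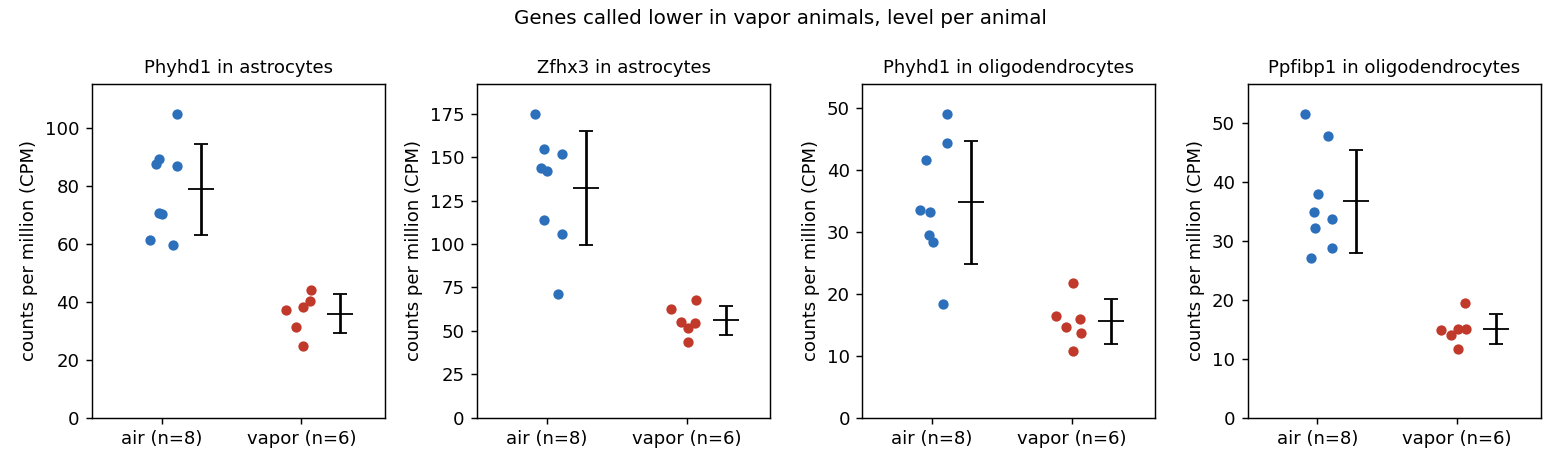
Level per animal in CPM (y axis, from 0) of the genes called by edgeR, Phyhd1 and Zfhx3 in astrocytes and Phyhd1 and Ppfibp1 in oligodendrocytes, with 1 dot per animal (air n = 8, vapor n = 6) and the mean ± SD beside the dots. Means were 36.0 against 79.0 for Phyhd1 and 56.0 against 132 for Zfhx3 in astrocytes, and 15.5 against 34.7 for Phyhd1 and 15.0 against 36.7 for Ppfibp1 in oligodendrocytes.

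No gene was called by edgeR in excitatory neurons, where 624 of 19372 genes had an unadjusted p under 0.05 and DESeq2 called 2. The genes with the smallest p were Baz1a, a chromatin remodelling subunit (3.42 ± 0.534 CPM in vapor, n = 6, and 5.37 ± 0.837 CPM in air animals, n = 8; log2 fold change -0.63 ± 0.13), and 2 genes of secreted proteins. These were the iron-binding Lcn2 (0.125 ± 0.0808 and 8.45 ± 10.6 CPM; -5.97 ± 1.22) and the dense-core vesicle component Scg2 (38.4 ± 8.56 and 53.4 ± 7.08 CPM; -0.46 ± 0.11), each with an adjusted p of 1.0. Gpc5 had a log2 fold change of 0.12 ± 0.11 and Cpa6 of -0.16 ± 0.31 there, neither called. In inhibitory neurons 1192 of 17843 genes had an unadjusted p under 0.05, edgeR called none and DESeq2 called 5. The smallest p there belonged to Lama2, a laminin chain (15.6 ± 3.10 and 24.8 ± 4.42 CPM; -0.67 ± 0.14), the chemokine Ccl5 (2.45 ± 1.01 and 1.08 ± 0.394 CPM; 1.20 ± 0.26) and the Wnt receptor Fzd2 (1.39 ± 0.365 and 2.96 ± 1.03 CPM; -1.07 ± 0.23). The adjusted p was 0.740 for each. DESeq2 gave an adjusted p under 0.05 to Baz1a and Lcn2 in excitatory neurons (0.0119 and 5.91e-05) and to Lama2, Ccl5 and Fzd2 in inhibitory neurons (0.0443 each). Gpc5 had a log2 fold change of -0.15 ± 0.11 in inhibitory neurons (adjusted p = 0.865). Clusters 8, 11, 22 and 24 held from 0.717% (animal 26) to 24.4% (animal 34) of inhibitory-named nuclei in vapor animals. In air animals they held from 1.27% (animal 20) to 56.3% (animal 19). The inhibitory values above, the interaction below and the class share given earlier include these nuclei. Whether the vapor effect differed between the 2 neuron classes was tested with the animal as a block, and 0 of 19184 genes passed in edgeR (smallest adjusted p = 0.704) and 0 in limma-voom. Of these genes 1354 had an unadjusted p under 0.05 in edgeR.

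Cpa6 in inhibitory neurons stood at 73.5 ± 87.3 CPM (SD, n = 6) in vapor and 232 ± 218 CPM (SD, n = 8) in air animals, a log2 fold change of -1.71 ± 0.80 (edgeR adjusted p = 0.740). Its levels overlapped between the groups, from 26.6 to 250 CPM in vapor and from 16.9 to 551 CPM in air animals. Cpa6 is one of the genes that lead cluster 8, at 1311 CPM against 53.1 CPM in all other nuclei, so its level in the class follows in part from the share of inhibitory-named nuclei in that cluster. This share ranged from 0.130% in vapor animal 2 to 33.6% in air animal 19. Its Pearson r with Cpa6 in the class was 0.989 over the 14 animals, 0.997 in the vapor and 0.985 in the air animals. Since cluster 8 is part of the class, some of this correlation is built in. Inside cluster 8, Cpa6 stood at 1160 ± 413 CPM (SD, n = 4) in vapor and 1273 ± 133 CPM (SD, n = 6) in air animals with at least 20 such nuclei (log2 fold change -0.16 ± 0.22, edgeR adjusted p = 1.0). Cpa6 (ENSMUSG00000042501) lies on chromosome 1 from 10324720 to 10719945 on the minus strand of GRCm38.

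**Figure D4:**
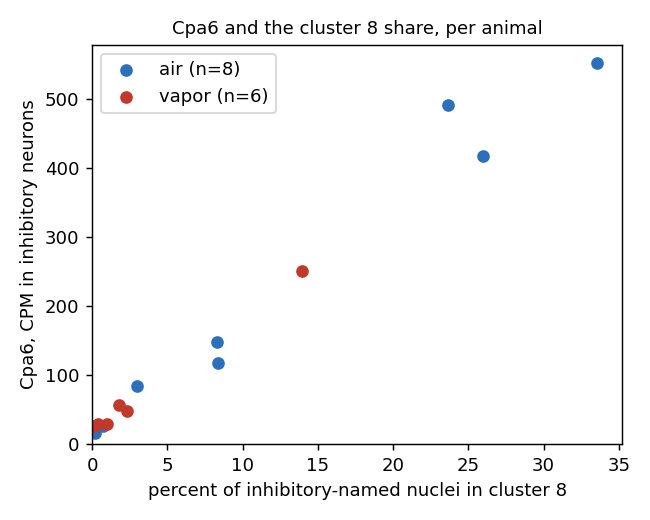
Cpa6 in CPM in inhibitory neurons (y axis) against the percent of inhibitory-named nuclei that fall in cluster 8 (x axis), with 1 dot per animal (air n = 8, vapor n = 6). Cpa6 leads cluster 8, which is part of the class, so both axes count the same nuclei, and its values range from 16.9 CPM to 551 CPM.

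In oligodendrocyte precursors, microglia and vascular cells edgeR called no gene. The smallest p in oligodendrocyte precursors belonged to the glial connexin Gjc3 (162 ± 28.9 CPM in vapor, n = 6, and 104 ± 18.4 CPM in air animals, n = 8; log2 fold change 0.63 ± 0.12, adjusted p = 0.799). Next were Zmat4 (132 ± 15.8 and 198 ± 38.6 CPM; -0.58 ± 0.13, adjusted p = 0.854) and Nckap5 (326 ± 65.8 and 208 ± 47.0 CPM; 0.65 ± 0.15, adjusted p = 0.854). In microglia it belonged to Actn2, an actin crosslinker (10.4 ± 1.30 and 19.9 ± 5.32 CPM; -0.93 ± 0.20). Next were the immune scaffold protein Bank1 (150 ± 48.8 and 79.3 ± 22.0 CPM; 0.90 ± 0.19) and the integrin subunit Itga9 (130 ± 29.5 and 81.5 ± 17.9 CPM; 0.67 ± 0.15), each with an adjusted p of 0.380. In vascular cells it belonged to the thiamine transporter Slc19a3 (81.1 ± 16.9 and 47.3 ± 8.14 CPM; 0.78 ± 0.14, adjusted p = 0.325). Depp1 (17.3 ± 5.02 and 6.65 ± 3.38 CPM; 1.34 ± 0.27, adjusted p = 0.371) and the long noncoding RNA Fendrr (39.2 ± 6.90 and 24.7 ± 4.31 CPM; 0.68 ± 0.14, adjusted p = 0.427) followed. DESeq2 gave an adjusted p under 0.05 to Gjc3 (0.0429), Bank1 (0.0486), Slc19a3 (0.00215), Depp1 (0.0112) and Fendrr (0.0468), and to none of the other 4. The genes with an unadjusted p under 0.05 numbered 638 of 13090, 647 of 12642 and 548 of 14186, and DESeq2 called 1, 4 and 8 genes. Gpc5 had a log2 fold change of 0.38 ± 0.17 in oligodendrocyte precursors, 0.20 ± 0.21 in microglia and 0.09 ± 0.17 in vascular cells, and Cpa6 of -0.91 ± 0.57, -0.85 ± 0.60 and -0.84 ± 0.64, none of them called. The microglial count was 1 without air animal 19 or air animal 21.

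At the level of the authors' types, edgeR called no gene in any of the 14 neuronal, macrophage and T cell types, with 348 to 1131 genes at an unadjusted p under 0.05. DESeq2 called 1 gene in each of Excit_D, Excit_F, Inhib_A and Inhib_C, 2 in Excit_E, 3 in the nuclei named T cells and 0 in the others. The edgeR count was 1 for Inhib_A without air animal 24 and 1 for the T cell type without vapor animal 34. Over all nuclei of each animal, edgeR called 0 of 21492 genes, 1212 had an unadjusted p under 0.05 and DESeq2 called 10. Lcn2 stood at 0.485 ± 0.332 CPM (SD, n = 6) in vapor and 18.5 ± 21.7 CPM (SD, n = 8) in air animals (log2 fold change -5.26 ± 1.11, edgeR adjusted p = 0.865, DESeq2 adjusted p = 0.00035). Lrg1, a secreted glycoprotein of the acute phase, stood at 0.496 ± 0.150 and 2.44 ± 2.62 CPM (-2.24 ± 0.62, edgeR adjusted p = 0.865). Both were chosen after their values were seen.

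Gene lists fixed before the data were examined were tested in each class, and 51 of 221 pairs of list and class passed in camera, 16 higher and 35 lower in vapor animals. None passed with an estimated correlation (smallest adjusted p = 0.920) or in fry (smallest adjusted p = 0.942). Calls of list members over all genes tested, or over a list alone, are those of edgeR unless DESeq2 is named. Mitochondrially encoded genes lay lower in all 7 classes in camera. In vascular cells all 13 were negative (median log2 fold change -0.61, camera adjusted p = 1.05e-12; adjusted p = 0.920 with an estimated correlation), with mt-Co3 at -0.71 ± 0.23 and mt-Co1 at -0.43 ± 0.20. There 6 of the 13, mt-Nd1, mt-Nd2, mt-Co2, mt-Atp6, mt-Co3 and mt-Nd4, passed when adjusted over the list alone, and 0 over all genes tested. Ribosomal protein genes lay lower in camera in excitatory and inhibitory neurons, astrocytes, oligodendrocyte precursors and vascular cells. In excitatory neurons all 80 were negative (median -0.25, camera adjusted p = 9.91e-06; adjusted p = 0.997 with an estimated correlation), with Rpl13 at -0.24 ± 0.25 and Rps29 at -0.37 ± 0.39. Mitochondrially encoded genes and the ribosomal gene Rplp1 also lead cluster 0, and the median mitochondrial percent of 0.238 in vapor and 0.331 in air animals stands beside them.

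Among glial and vascular lists, myelin genes lay higher in oligodendrocytes of vapor animals in camera, with 18 of 20 positive (median 0.31, camera adjusted p = 1.15e-06; adjusted p = 0.920 with an estimated correlation). Mbp had a log2 fold change of 0.20 ± 0.14, and 0 members passed when adjusted over the list alone or over all genes tested, while DESeq2 called the member Ugt8a, a galactolipid synthesis enzyme (0.57, DESeq2 adjusted p = 0.0480). In the same nuclei DESeq2 called lower values of 5 genes known from neurons, which edgeR did not call and which were chosen after their values were seen. Their log2 fold changes were -1.10 for Dlgap1, -1.71 for Kcnb2, -1.55 for Epha6, -0.82 for Lrrtm4 and -1.47 for Kcnd2 (DESeq2 adjusted p = 0.0324, 0.0444, 0.0271, 0.0457 and 0.0492). Beside the list also stand Cpa6 in these nuclei, at 57.6 and 244 CPM, and cluster 4, with 6.70 ± 1.38% of nuclei in vapor (n = 6) and 4.75 ± 1.64% in air animals (n = 8; exact p = 0.0363, adjusted p = 0.265 over the clusters). Genes of oligodendrocyte differentiation lay higher in oligodendrocyte precursors, with 14 of 16 positive (median 0.29, camera adjusted p = 1.15e-06; adjusted p = 0.920 with an estimated correlation). There Ptprz1 (0.42 ± 0.14), Sox6 (0.48 ± 0.17) and Cspg4 (0.50 ± 0.16), all known from the precursor stage, passed when adjusted over the list alone and 0 over all genes tested. Interferon-stimulated genes lay higher in vascular cells, with 24 of 27 positive (median 0.27, camera adjusted p = 1.06e-10; adjusted p = 0.920 with an estimated correlation). They did so in microglia too, with 14 of 16 positive (median 0.20, camera adjusted p = 6.1e-05; adjusted p = 0.920 with an estimated correlation). None of their members passed when adjusted over the list alone or over all genes tested in edgeR, and DESeq2 called none of them over all genes tested. The most abundant in vascular cells, the antigen presentation genes H2-D1 and H2-K1, had a log2 fold change of 0.02 ± 0.26 and -0.10 ± 0.28. Blood-brain barrier genes lay higher in vascular cells, with 17 of 19 positive (median 0.23, camera adjusted p = 1.92e-05; adjusted p = 0.920 with an estimated correlation). Lrp8 (0.41 ± 0.11) passed when adjusted over the list alone and 0 over all genes tested, and the most abundant members, Flt1 and Slco1a4, had a log2 fold change of 0.32 ± 0.15 and 0.01 ± 0.17. Beside these lists, markers of red cells and blood lay higher in camera in microglia (5 of 6 positive, median 0.66, adjusted p = 0.0216) and in oligodendrocyte precursors (5 of 5, camera adjusted p = 0.0109), and myelin genes lay lower in vascular cells (12 of 16 negative, median -0.18, camera adjusted p = 0.0345). With an estimated correlation the adjusted p was 0.920 for each of the 3.

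Lists with lower values included the reactive astrocyte genes in astrocytes, with 13 of 14 negative (median -0.39, camera adjusted p = 0.00603; adjusted p = 0.920 with an estimated correlation). Cp (-0.92 ± 0.27) and the metallothionein Mt2 (-0.68 ± 0.22) were lower and S1pr3 (0.50 ± 0.17) higher when adjusted over the list alone, and 0 passed over all genes tested. Markers of meningeal fibroblasts lay lower in nuclei named astrocytes, with 7 of 8 negative (median -0.87, camera adjusted p = 0.000831; adjusted p = 0.920 with an estimated correlation). Of them Ptgds (-1.10 ± 0.31), Col1a2 (-0.83 ± 0.21), Slc6a13 (-1.55 ± 0.45) and Igf2 (-0.92 ± 0.33) passed when adjusted over the list alone, and 0 over all genes tested in edgeR, while DESeq2 called Ptgds (DESeq2 adjusted p = 0.0490). Beside both lists stands cluster 20, led by Bnc2, Bmp6, Ranbp3l, Slc6a13 and Ptgds, which held 0.865 ± 0.244% of nuclei in vapor (n = 6) and 1.96 ± 1.16% in air animals (n = 8; exact p = 0.0476, adjusted p = 0.265 over the clusters). Glucocorticoid-responsive genes lay lower in inhibitory neurons, with 18 of 20 negative (median -0.29, camera adjusted p = 0.000741; adjusted p = 0.920 with an estimated correlation). Lcn2 (-5.55 ± 1.30) and Plin4 (-0.98 ± 0.30) passed when adjusted over the list alone, and 0 over all genes tested in edgeR, while DESeq2 called Lcn2 (DESeq2 adjusted p = 0.000865). In the same nuclei the meningeal fibroblast markers (8 of 9 negative, median -0.85, camera adjusted p = 0.000988) and astrocyte transport and homeostasis genes (18 of 22 negative, median -0.27, camera adjusted p = 0.00206) also lay lower, each with an adjusted p of 0.920 with an estimated correlation. Activity-regulated immediate early genes did not pass in any class, and in excitatory neurons 17 of 30 were positive (camera adjusted p = 0.706), with Homer1 at 0.25 ± 0.15 and Nr4a1 at 0.08 ± 0.14. Adjusted over the list alone, Scg2 (-0.46 ± 0.11) passed 0.05 in excitatory neurons, Scg2 (-0.57 ± 0.16) and the pentraxin Nptx2 (-0.55 ± 0.15) in astrocytes, and no member in the other classes. The GABA-A receptor subunits did not pass in excitatory or inhibitory neurons (camera adjusted p = 0.808 and 0.987), with Gabrg3 at 0.20 ± 0.09 in excitatory neurons. The ethanol and acetaldehyde metabolism genes did not pass in any class. In microglia Acss1 (0.51 ± 0.16) and Acss2 (-0.42 ± 0.14), which make acetyl-CoA from acetate, passed in opposite directions when adjusted over the list alone, and 0 over all genes tested.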

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

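The tests of Cpa6 and Lcn2 in this part were chosen after their results were seen. In 11 of 126 groups of animals 1 animal lay far from the rest of its group by Dixon's criterion, which chance gives in about 1 in 20 independent groups. These groups were not independent, since the same gene in the same animals was counted in several classes, so this rate is only a guide. Vapor animal 34 accounted for 8 of the 11. In it Cpa6 stood at 250 CPM in inhibitory neurons (nearest vapor animal 57.0), 173 CPM in oligodendrocytes (64.6), 141 CPM in microglia (43.5), 103 CPM in excitatory neurons (58.2), 95.2 CPM in oligodendrocyte precursors (47.5) and 51.3 CPM in vascular cells (21.5). Its Gpc5 in inhibitory neurons was 117 CPM (nearest 161), and its share of Inhib_C nuclei 5.26% (nearest 4.02%). Air animal 20 had 7.03% of nuclei named T cells (nearest air animal 5.54%) and 7.96 CPM of Lrg1 over all nuclei (nearest 3.91). Vapor animal 26 had 1.12 CPM of Lcn2 over all nuclei (nearest vapor animal 0.490).

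Cpa6 averaged 73.5 CPM in inhibitory neurons of vapor and 232 CPM in those of air animals, and vapor animal 34 also had the highest share of clusters 8, 11, 22 and 24 among vapor animals, at 12.2%. A change of Cpa6 inside cluster 8 is argued against, since its log2 fold change there was -0.162, with a 95% interval from -0.67 to 0.34. A candidate explanation is olfactory bulb tissue in some punches, but without those 4 clusters the log2 fold change of Cpa6 in the class was still -1.20, which is 0.706 of its -1.71, between the bounds set for and against it. Free RNA of the same nuclei in other droplets, which leaving out clusters would not remove, was not tested. An effect of vapor on Cpa6 outside cluster 8, a smaller one inside it, or one on the number of nuclei in the 4 clusters (exact p = 0.101 for their share) stays open.

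Lcn2 over all nuclei was above 10 CPM in air animals 17 (45.3), 20 (53.1), 21 (13.3) and 22 (31.3), between 0.603 and 2.30 CPM in air animals 5, 19, 24 and 29, and at most 1.12 CPM in the vapor animals. Blood neutrophils, which carry much S100a8 and S100a9, are argued against as the whole source in air animals 17, 20 and 22. There both together were 0.0852, 0.110 and 0.0690 of the Lcn2 level, under the bound of 0.5 by more than counting error. The ratio in neutrophils themselves was not measured here, so this bound is an assumption. Neutrophils stay open in air animal 21 (0.524), where the neutrophil genes Ngp (1.38 CPM) and Ltf (0.757 CPM) lay above every vapor animal. Ngp (0.611 CPM), Ltf (0.340 CPM) and Camp did so in air animal 17, while in air animals 20 and 22 all 3 lay within or below the range of the vapor animals. S100a8 and S100a9 lay above every vapor animal in air animals 17 (1.66 and 2.20 CPM), 20 (2.75 and 3.08 CPM) and 21 (2.76 and 4.23 CPM). In air animal 22 they did not (0.896 and 1.26 CPM). Endothelial Lcn2 stays open as a candidate source, since Lcn2 in the vascular cluster 7 was 4.22, 6.12, 3.35 and 11.5 times that in the other nuclei of air animals 17, 20, 21 and 22, and not over 5 times in each. An inflammatory response in individual animals that is unrelated to vapor, and an effect of vapor, both stay open and were not tested, and edgeR did not call the difference (adjusted p = 0.865) while DESeq2 did (adjusted p = 0.00035).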

How the results depend on the processing

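The alternatives that regroup or leave out nuclei by cluster, leave out the 5 animals with over 10% of nuclei in clusters 8, 11, 22 and 24, or use that share as a covariate were chosen after the data were seen. No paired analysis was possible because the groups share no animal numbers. RLE normalization moved no count of called genes past 1.5 times, and a minimum of 50 nuclei left out no animal and so tested nothing. Phyhd1 in astrocytes stayed past its threshold under every alternative run, with a highest adjusted p of 0.0260. In simulated counts 24.2% of 1.5-fold and 69.8% of 2-fold changes were recovered in oligodendrocytes and 37.9% and 81.5% in microglia, so changes of these sizes were not detectable in every gene at this depth. Except where fewer animals were used, the cause of each change given here was not tested.

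The 2 astrocyte calls became 40 with DESeq2, 4 with no expression filter, 4 with the median UMIs as a covariate, 4 at a threshold of 0.1, 4 without cluster 0, 4 with nuclei whose name and cluster matched, and 1 without the 5 animals. They lay between 2 and 7 with 1 animal left out. The 2 oligodendrocyte calls became 46 with DESeq2, 13 with no expression filter, 6 at a threshold of 0.1, 1 when adjusted over all classes together, 8 without the mixed clusters and 0 with the share covariate. They lay between 0 and 6 with 1 animal left out. Of counts that were 0 in edgeR, DESeq2 gave 10 for all nuclei, 2 for excitatory neurons, 5 for inhibitory neurons, 1 for oligodendrocyte precursors, 4 for microglia, and 8 for vascular cells. Among types it gave 1 each for Excit_D, Excit_F, Inhib_A and Inhib_C, 2 for Excit_E and 3 for the T cell type. Microglia gave 2 with no expression filter and 0 to 1 with 1 animal left out, Inhib_A 1 with the share covariate and 0 to 1 with 1 animal left out, and the T cell type 0 to 1 with 1 animal left out. The 51 list and class pairs became 0 with an estimated correlation and 0 in fry.

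Of named genes that edgeR did not call, DESeq2 called Baz1a (adjusted p = 0.0119) and Lcn2 (5.91e-05) in excitatory neurons, Lama2, Ccl5 and Fzd2 (0.0443 each) in inhibitory neurons, Gjc3 (0.0429) in oligodendrocyte precursors, Bank1 (0.0486) in microglia, Slc19a3 (0.00215), Depp1 (0.0112) and Fendrr (0.0468) in vascular cells, and Lcn2 (0.00035) in all nuclei. Of the named calls, Zfhx3 in astrocytes was lost without the 5 animals (-0.99, adjusted p = 0.172, range over its alternatives 1.09e-08 to 0.172). Ppfibp1 in oligodendrocytes was lost without vapor animal 2, 33 or 34 (-1.21, -1.26 and -1.28, adjusted p = 0.0693, 0.0605 and 0.0502) and with the share covariate (-1.25, adjusted p = 0.0639), where its log2 fold change stayed close to the -1.28 of all animals. It was also lost with classes from clusters (-0.54, adjusted p = 0.999) and with matched nuclei (-0.46). Phyhd1 in oligodendrocytes was lost without any of vapor animals 2, 9, 16, 33 and 34 and air animals 17, 19, 20, 21 and 22 (-1.26 to -1.13, adjusted p from 0.0578 to 0.193), with the share covariate (-1.25, adjusted p = 0.138) and without the 5 animals (-1.20, adjusted p = 0.159). In each of these its log2 fold change stayed close to the -1.23 of all animals, and the call ended by the adjusted p.

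Cpa6 in excitatory neurons turned positive with the share covariate (0.32), without the 4 clusters (0.0012), without the mixed clusters (0.0307), without the 5 animals (0.13), with classes from clusters (0.22) and with matched nuclei (0.29). It spanned -0.42 to 0.048 with 1 animal left out. Gpc5 in oligodendrocytes turned negative with the share covariate (-0.14), without the 4 clusters (-0.063) and with classes from clusters (-0.0825), and spanned -0.11 to 0.12 with 1 animal left out. The added alternatives also gave -0.0271 and -0.0115 for Gpc5 in oligodendrocyte precursors, -0.0675, -0.26 and -0.27 for Gpc5 in microglia, 0.0334 for Cpa6 in oligodendrocyte precursors, 0.0922 for Cpa6 in microglia and 0.0393 for Ppfibp1 in astrocytes. None of these values was a call.

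The share difference (vapor minus air, percentage points) changed sign without the 4 clusters for astrocytes (-0.67), microglia (-0.20), Excit_A (-0.18), Excit_B (-0.15), Excit_C (-0.0942) and Inhib_B (0.30), without cluster 0 for Excit_A (-0.0505), Excit_B (-0.0547) and Inhib_E (0.0366), and with at least 1000 UMIs for Excit_B (-0.0117). With 1 animal left out it spanned -0.19 to 0.20 for astrocytes, -0.11 to 0.31 for microglia, -0.0415 to 0.33 for Excit_A, -0.11 to 0.26 for Excit_B, and -0.0673 to 0.28 for Excit_C. It spanned -0.066 to 0.35 for Inhib_D, -0.43 to 0.0034 for Inhib_E and -0.30 to 0.0922 for the T cell type. It passed adjustment for oligodendrocyte precursors without air animal 17 (-0.87, range -0.87 to -0.55) and for Excit_F without vapor animal 34 (2.41, range 1.53 to 2.41). Counted as pairs of a result and an alternative, 309 planned and 33 added pairs kept the direction and side of the threshold for share differences, and 665 and 224 did for named genes.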

Other observations

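The tests of Phyhd1 and the bulb and neutrophil marker lists in this part were chosen after the results were seen, and the counts over splits of the animals were set before. Spp1, which encodes the secreted protein osteopontin and belongs to the fixed microglial list, was not called by edgeR over all genes tested. DESeq2 called it in astrocytes (-1.54, adjusted p = 0.00178), all nuclei (-1.23, adjusted p = 0.0359), Inhib_C (-1.80, adjusted p = 0.0134) and the T cell type (adjusted p = 0.0140). Among the alternatives, edgeR called it in astrocytes with no expression filter (adjusted p = 0.0236) and without air animal 24 (adjusted p = 0.0188), and in the T cell type without vapor animal 34 (adjusted p = 0.0408). Adjusted over the list alone in edgeR it was lower in vapor animals in astrocytes (-1.54 ± 0.29, adjusted p = 0.000727), inhibitory neurons (-1.15 ± 0.31, adjusted p = 0.0338) and excitatory neurons (-1.15 ± 0.32, adjusted p = 0.04997). Beside it in these 3 classes, meningeal fibroblast markers lay lower in camera, with 7 of 8, 8 of 9 and 9 of 9 negative (medians -0.87, -0.85 and -0.46, camera adjusted p = 0.000831, 0.000988 and 0.0396; adjusted p = 0.920, 0.920 and 0.993 with an estimated correlation). Cluster 20, led by Bnc2 and Bmp6, held 0.865% of nuclei in vapor and 1.96% in air animals (exact p = 0.0476, adjusted p = 0.265). Potassium channel genes lay lower in oligodendrocytes in camera, with 24 of 30 negative (median -0.22, camera adjusted p = 0.000831; adjusted p = 0.920 with an estimated correlation). Beside them, DESeq2 called lower values there of the channels Kcnb2 (-1.71) and Kcnd2 (-1.47) and of other genes known from neurons, Dlgap1 (-1.10), Epha6 (-1.55) and Lrrtm4 (-0.82), all chosen after their values were seen. Myelin genes lay higher in the same nuclei, with 18 of 20 positive, and cluster 4 held 6.70% of nuclei in vapor and 4.75% in air animals (exact p = 0.0363, adjusted p = 0.265). Nuclear-encoded genes of oxidative phosphorylation lay lower in excitatory neurons, with all 36 negative (median -0.16, camera adjusted p = 0.00211; adjusted p = 0.997 with an estimated correlation).

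Phyhd1 was lower in vapor animals in both glial classes. In astrocytes its log2 fold change kept 0.992 of its value with the share of clusters 8, 11, 22 and 24 as a covariate, past the threshold, which argues against that share as the whole cause. With the median UMIs as a covariate it kept 0.985, also past the threshold. The median UMIs were close between the groups (4413 ± 1078 in vapor and 4204 ± 1015 in air animals, exact p = 0.714). A covariate so balanced could hardly move the fold change, so no conclusion is drawn from it. In oligodendrocytes Phyhd1 kept 0.994 with the median UMIs, which decides as little. It kept 1.06 without the nuclei of clusters 8, 11, 22 and 24 (-1.30 ± 0.20, adjusted p = 0.0267, range over its alternatives 0.00154 to 0.193), where Cpa6 went from -2.12 to -1.29, which argues against those nuclei as the whole cause. With the share as a covariate Phyhd1 kept 1.02 (-1.23 ± 0.20 before and -1.25 ± 0.22 after). The fold change did not shrink, which argues against a trend with the share as the whole cause. The call ended because the larger error raised the edgeR p from 5.35e-06 to 2.2e-05 (adjusted p = 0.138). The rule set for this test also asked that the call be kept, so by that rule it stayed undecided. Astrocyte RNA as the whole source is argued against, since Phyhd1 in cluster 4 relative to cluster 5 was 3.26 times what Slc1a2, the astrocytic glutamate transporter, gave in the median air animal and 2.38 times in the lowest, and 3.07 times in the median vapor animal, though 1.42 times in vapor animal 34, which alone lay under the 1.5 set for this source. This rests on Slc1a2 alone and assumes that astrocyte RNA in cluster 4 had the gene mix of cluster 5, which was not checked. A direct effect of vapor on Phyhd1 in both glial classes is a hypothesis that these data leave open, as is a difference between the animals' punches that no covariate measured.

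For clusters 8, 11 and 22 a candidate source is olfactory bulb. Its marker lists were written after the leading genes of the clusters were known, Cdhr1 and Th among them, so they describe the clusters and cannot test the source. All 5 mitral and tufted cell markers were at least 10-fold higher in cluster 22 than in other nuclei, led by Cdhr1 at 201 and 3.01 CPM. Of the 5, 0 reached 20 CPM in other nuclei or stood in a fixed list. Of the granule cell markers 3 of 5 were so in cluster 8 and 1 of 5 in cluster 11, with Meis2 most abundant at 3415 and 436 CPM in cluster 8. Of the 5, 2 reached 20 CPM in the nuclei outside cluster 8 and 3 in those outside cluster 11, and 1 stood in a fixed list. Of the dopaminergic periglomerular markers 2 of 4 were so in cluster 11, with Th at 62.6 and 2.55 CPM, and 1 of 4, Ddc, in each of the vascular clusters 7 and 18, at 67.6 and 72.1 CPM (17.0- and 20.6-fold). Of 8 neutrophil markers 0 were so in cluster 7 and 1 in cluster 18. The test that bears on the bulb as a cause of a difference between the groups is that of Cpa6, which kept 0.706 of its fold without clusters 8, 11, 22 and 24.

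Other splits of the 14 animals into 6 and 8 were compared with the real one. In astrocytes 3 of 100 splits, the real one included, gave at least the 2 real calls, and in oligodendrocytes 1 of 100. Both shares lay under 0.05 but were not adjusted over the classes and types tested, so chance is not excluded. The oligodendrocyte count was also 0 without vapor animal 2, 33 or 34. The highest other count was 1 in oligodendrocytes and 147 in astrocytes, from a split that set air animals 5, 19, 20, 21, 22 and 29 against all 6 vapor animals and air animals 17 and 24, with 15.8% of nuclei in clusters 8, 11, 22 and 24 against 3.34%. Such a count points to a structure of the samples, which was not separated from the groups, since this split lies close to them. Where the real count was 0 every split gives as many, 100 of 100 for the other classes, 60 of 60 for each of the authors' types and 40 of 40 for the interaction, which says nothing about chance. The highest other counts were 1 for all nuclei, 0 for excitatory neurons, 2 for inhibitory neurons, 2 for oligodendrocyte precursors, 1 for microglia and 13 for vascular cells. Among the types they were 649 in Inhib_C, 215 in Excit_B, 9 in Inhib_A, 4 in Excit_D and in macrophages, 1 in Excit_E, Excit_F and Inhib_F, and 0 in the others, as for the interaction. The Inhib_C split set air animals 5, 17, 19, 21, 22 and 29 against all 6 vapor animals and air animals 20 and 24 (16.4% against 2.87% in the 4 clusters), so its structure was not separated from the groups either. The Excit_B split put vapor animals 2, 9 and 33 and air animals 19, 22 and 24 together (9.99% against 7.67%), and its count points to a structure of the samples too. For the gene lists 18 of 40 splits gave at least the real 51 pairs (highest other 118), so chance cannot be excluded for the camera results.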
